A study of Mus musculus with 3 samples.

How the data were processed

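Single-cell RNA was measured in sorted bone marrow mesenchymal stromal cells of C57BL/6 mice aged 6 to 8 weeks, per the labels. There were 3 libraries and 1 per genotype: WT, R76W and D130. Per the labels, marrow cells were freed with collagenase, red cells were lysed, and the cells were stained for CD31, CD45, Ter119, CD51 and PDGFRα before sorting and 10x Genomics 3′ v3 library preparation. Whether several mice were pooled is not stated.

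The deposited matrices hold raw UMI counts per gene and barcode, per the file headers written by Cell Ranger 7.0.1, and the submitters' processing notes name Cell Ranger, Seurat and genome build mm10. The values were checked to be whole numbers, and the lowest total of a barcode was 500 UMIs in each library. Only the count matrices were used here, and cell names were rebuilt from them. Gene positions and lengths came from the GENCODE annotation of GRCm38 (mm10), with 1-based coordinates. Genes listed under 1 symbol with several identifiers were summed, a choice made after a first clustering was seen.

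Work was done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes. Doublets were called per library with Scrublet at an expected rate of 0.06 and removed. Where the automatic threshold marked under 0.5% of a library, the top 0.8% of cells per 1000 cells by score were removed instead, which applied to WT alone. The removed doublets were 153 in WT (3.50%), 15 in R76W (0.838%) and 32 in D130 (1.47%), and 8136 cells were used.

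All libraries were clustered together without batch integration, since library and genotype are the same. UMIs were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering used 15 neighbours, resolution 1 and seed 0. A first clustering had stopped after 2 Leiden iterations, and its LepR+ clusters differed from those of a second run on summed symbols. Iterating until the clusters no longer moved was chosen after both were seen, and the clusters within the LepR+ class are therefore less stable than the classes. A cluster took the name of the cell class whose markers were highest over other cells, among 22 classes, with a mean log2 level at least 3 above the lower quartile of clusters and at least 3 markers detected. A name was withheld where mesenchymal and other markers both passed, where the 10 leading genes held more markers of another class, or where UMIs were low and no leading gene was a marker of the class. Markers and gene lists were fixed before the data were examined. The rule from markers to names, with its score limits, was written after marker levels of the clusters had been seen. A first form took leading genes over all other cells and left clusters 8, 10 and 16 unnamed, and it was then replaced by leading genes over cells of other classes. The first form was kept as an alternative.

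The mesenchymal class with the most cells, LepR+ stromal cells, was the main class for gene levels. UMIs were summed over the class in each library and divided by its total (CPM), and log2 ratios used a pseudocount of 1 CPM. Measured genes had at least 30 UMIs over the 3 libraries, which gave 13164 genes. With 1 library per genotype no test between genotypes was possible. CPM carry exact Poisson intervals, shares carry exact Clopper-Pearson intervals, and ratios carry the interval of a conditional binomial, all at 95% and all for counting error only. Where a library had no UMI of a gene, the log2 ratio rested on the pseudocount alone. Counts under 3 were raised to a floor of 3 only in a separate version of the list medians.

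Gene lists covered 27 functions, and each list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Members at least 1.5 times higher or lower were counted as sizes. The lists were adipogenic, osteogenic, prostaglandin E2, cAMP and CREB targets, connexins, Wnt, niche factors, osteoclast regulation, stem or progenitor, senescence, cell cycle, immediate early, heat shock, unfolded protein response, interferon, inflammatory chemokines, oxidative stress, glycolysis, nuclear oxidative phosphorylation, extracellular matrix, TGF-beta and BMP, Notch, IGF, cholesterol synthesis, mitochondrially encoded, ribosomal and sex-linked genes. A further list that was fixed with these is not reported here.

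Named genes followed a rule fixed before the data were examined. Among genes with at least 50 UMIs in the compared libraries, UMIs in at least 20 cells, at least 20 CPM in 1 library and Poisson intervals that did not overlap, the 8 highest and 8 lowest ratios were named, without mitochondrial, ribosomal, hemoglobin, immunoglobulin, sex-linked and blood or endothelial marker genes. Up to 4 members of each list past 1.5 times, and 16 genes of the study's question, were added. The 8 lowest ratios were also taken without genes that were higher in erythroid than in LepR+ cells in each of the 3 libraries. This was added after the values were seen, and a gene higher in erythroid cells of WT alone could stay.

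The steps were tested on Poisson counts simulated at the LepR+ totals of these libraries, with a known change given to 200 of 13164 genes, all with at least 300 UMIs. The simulation held no variation between animals, no co-expression of list members and no differing mixture of clusters. For R76W against WT, D130 against WT and D130 against R76W, genes changed 1.5 times were recovered in the right direction with separated intervals in 94.0%, 95.5% and 97.0% of 67 genes. For 2 times the shares were 100%, 98.5% and 100% of 67 genes, and for 4 times 100% of 66 genes in each comparison. Of 200 unchanged lists, 4%, 3% and 5.5% fell outside percentiles 2.5 to 97.5, and a list of 30 genes raised 1.3 times stood at percentile 100 in each comparison. The unchanged lists were random draws like those they were ranked against. Their share outside therefore follows from construction and does not show how often real lists would fall there.

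Depth was 81837778 UMIs in WT, 29558251 in R76W and 46897983 in D130, and the class totals behind LepR+ gene levels were 7234452, 8594783 and 7777154 UMIs. Alternatives fixed before the data were examined changed the mitochondrial, gene and UMI limits, doublet removal, Leiden resolution, joint clustering, depth per cell, the minimum of UMIs per gene, the pseudocount, the scaling and the choice of cells. Alternatives chosen after seeing the data changed the naming rule and the genes used for clustering, subtracted erythroid RNA, kept LepR+ cells with at most 1 hemoglobin UMI, weighted LepR+ clusters equally, left out cluster 2 or cluster 18, and removed a trend with gene length. Erythroid RNA was subtracted with each library's own erythroid profile, scaled to the erythroid markers seen in the class. Percentiles were also taken after a gene length trend in 10 bins was removed.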

Results

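Single-cell 3′ RNA libraries were made from sorted bone marrow stromal cells of mice that carry osteocyte-directed mutants of connexin 43 (Cx43, gene Gja1), the main gap junction and hemichannel protein of osteocytes. R76W inhibits gap junctions between osteocytes, and the deletion of residues 130 to 136, as which the label D130 was read, blocks both gap junctions and hemichannels. WT mice were the control. Each genotype had 1 library and there were no replicates, so every difference is one between libraries and no spread between animals could be given. WT held 7352 barcodes and 81837778 UMIs, R76W held 3317 barcodes and 29558251 UMIs, and D130 held 4245 barcodes and 46897983 UMIs. After the limits on genes, UMIs, mitochondrial share and doublets, 4218 WT cells (median 10440.5 UMIs), 1775 R76W cells (9331 UMIs) and 2143 D130 cells (11676 UMIs) were used. Intervals are 95% and cover counting error only.

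LepR+ stromal cells support blood stem cells and give rise to adipocytes and osteoblasts, and they made up most mesenchymal cells of WT, R76W and D130. Erythroid cells were present after the sort, at the UMI and mitochondrial limits used, and were the largest class in WT. Mesenchymal cells were 40.3% (38.8 to 41.8) of WT cells, 71.7% (69.5 to 73.7) of R76W cells and 57.3% (55.2 to 59.4) of D130 cells. Erythroid cells were 54.1% (52.6 to 55.7) in WT, 20.6% (18.7 to 22.5) in R76W and 28.5% (26.6 to 30.5) in D130. Among cells that were not erythroid, the mesenchymal share was 87.8% (86.3 to 89.3) in WT, 90.2% (88.5 to 91.7) in R76W and 80.2% (78.1 to 82.1) in D130. Monocytes or macrophages were 1.42%, 3.21% and 5.88% of WT, R76W and D130 cells, and neutrophils were 1.47%, 3.15% and 5.32%. These shares are of all cells with erythroid cells included, so part of their difference from WT follows from the larger erythroid share of WT. Cluster 15, with markers of stromal and erythroid cells together, was left unnamed and held 2.68%, 1.41% and 2.99%.

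Among mesenchymal cells, LepR+ stromal cells were 70.7% (68.5 to 72.8) in WT, 80.3% (78.0 to 82.4) in R76W and 72.7% (70.1 to 75.2) in D130. Osteolineage cells were 27.3% (25.2 to 29.5) in WT, 17.8% (15.7 to 19.98) in R76W and 25.5% (23.1 to 28.0) in D130, and the WT and D130 intervals overlapped. The osteolineage share depended on the clustering: in 8 of 10 other settings it was 18.8% to 20.7% in WT, and R76W was lowest in each of the 10. Fibroblasts were 2.00%, 1.97% and 1.79%. The osteolineage class held Wif1-rich and Spp1-rich cluster 5 (334 WT, 136 R76W and 179 D130 cells) and Bglap-rich osteoblasts of cluster 11 (130, 90 and 134 cells). Cluster 11 was 28.0% (24.0 to 32.3) of the osteolineage class in WT, 39.8% (33.4 to 46.5) in R76W and 42.8% (37.3 to 48.5) in D130. The LepR+ class was spread differently over its clusters in each library. Cluster 1, with high Ccl2 and high immediate early genes (Fosb, Egr1, Jun and Fos), held 29.7% of WT, 18.2% of R76W and 48.2% of D130 LepR+ cells. Such genes also respond to cell dissociation, and whether the cluster reflects it was not tested. Cluster 2, with high Aldh1a2 and Ptn, held 20.8%, 50.7% and 6.49% of the LepR+ cells, and so was mostly cells of 1 library and not clearly a cell type. Cluster 4 held 25.3%, 9.89% and 29.9%, and cluster 10, with high A2m, Bmp4 and Mmp13, held 17.6%, 14.99% and 5.26%.

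**Figure D1:**
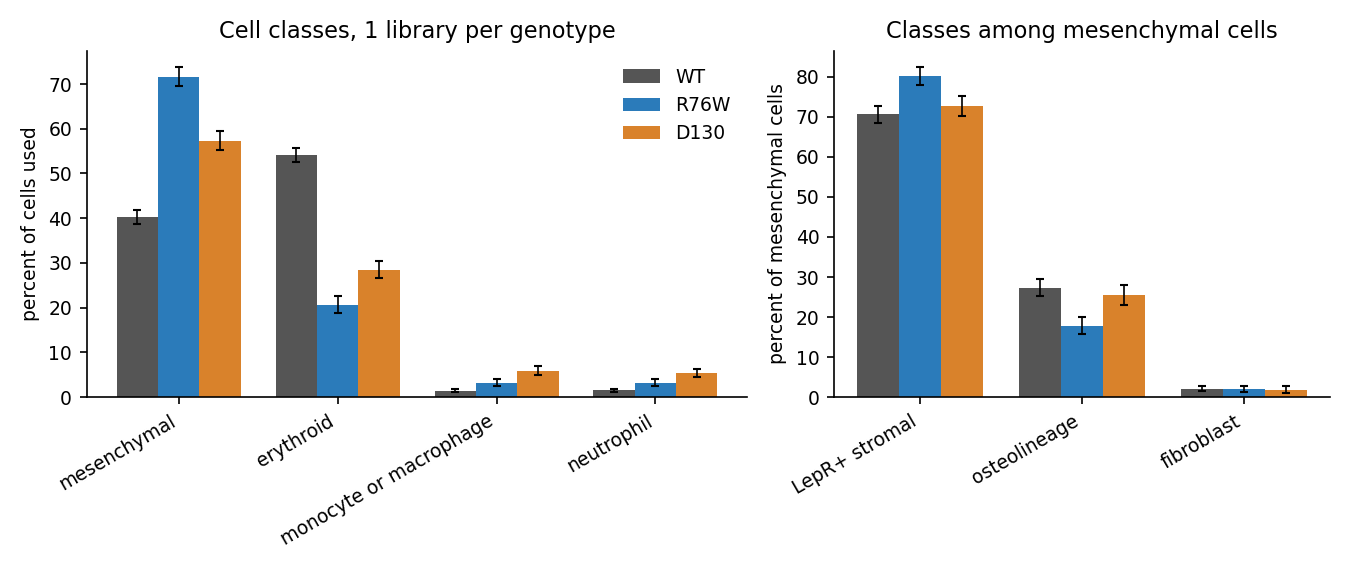
Percent of cells used in each class (left) and percent of mesenchymal cells in each mesenchymal class (right), 1 bar per library of WT, R76W and D130, with exact Clopper-Pearson 95% intervals as error bars. Erythroid cells were 54.1% of WT cells, and the osteolineage share was lowest in R76W at 17.8%.

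RNA of erythroid cells was present in WT stromal cells at a higher level than in the mutant libraries. Hemoglobin genes summed to 2091 CPM in WT LepR+ cells, 224 in R76W and 229.5 in D130, against 38044, 21824 and 22008 CPM in the erythroid cells of the same libraries. Erythroid RNA was estimated at 3.88% of the LepR+ UMIs in WT, 0.378% in R76W and 0.639% in D130, and at 11.3%, 0.254% and 1.02% in osteoblasts of cluster 11. These are shares of summed UMIs and were not even over cells. In WT cluster 11, 13 of 130 cells, those with at least 50 cell cycle UMIs per 10000, held a median of 706 hemoglobin UMIs against 2 in the others. Neutrophil markers summed to 109 CPM in WT LepR+ cells, 86.6 in R76W and 92.7 in D130, monocyte markers to 45.3, 57.7 and 80.6, and endothelial markers to 56.8, 95.2 and 84.5. The endothelial markers include Fabp4, which the adipogenic list also holds and which made up most of their sum in WT and D130. Genes that erythroid cells express strongly are therefore given with their erythroid level.

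R76W against WT asks how stromal cells differ when osteocyte gap junctions are inhibited and hemichannels are kept. LepR+ cells of R76W had more RNA of Gja1, of the matrix gene Col8a1, and of cAMP-responsive genes such as the nuclear receptor Nr4a1. They had less of Spp1 (osteopontin), of Bmp4, of the prostaglandin-degrading enzyme gene Hpgd and, by the median of the list, of interferon-response genes. In the cells taken as LepR+, the adipogenic and osteogenic lists as a whole stood near WT, although Pparg and Adipoq were lower in R76W. Cluster 2 held 50.7% of the R76W LepR+ cells and cluster 1 was the largest in WT, so levels are of different mixtures of clusters.

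Gja1 (ENSMUSG00000050953, chromosome 10, 56377330 to 56402513, GRCm38) was at 737 (717 to 757) CPM in WT LepR+ cells and 1174 (1151 to 1197) CPM in R76W, 1.59 times higher (log2 ratio 0.67). The transgenes are directed to osteocytes, so Gja1 counts in sorted stromal cells do not check the mutation. Whether any of these counts came from a transgene was not tested. Within clusters, Gja1 was at 639 CPM in WT and 1013 in R76W in cluster 1, and at 822 and 1252 in cluster 2. The connexin and pannexin list had a median log2 ratio of 0.29 (percentile 97.0).

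Among adipogenic genes, the regulator Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399) was at 267 (255 to 279) CPM in WT and 196 (187 to 206) CPM in R76W, and Adipoq (adiponectin) at 1520.1 and 1013 CPM. Apoe was at 3335 CPM in WT and 2205 in R76W, Cfd at 7.74 and 0.465, and Klf15 at 10.4 and 19.1. Lepr was at 2132 and 2462 CPM and the niche chemokine Cxcl12 at 17679 and 16056 CPM (log2 ratio -0.14, which was 0.04 over all mesenchymal cells). The adipogenic list had a median of -0.02 at percentile 31.9, with 2 of 30 genes at least 1.5 times higher and 3 lower. For the osteogenic list the median was -0.01 at percentile 28.7, with 2 of 33 genes higher and 4 lower, but it was 0.36 with each library clustered on its own and 0.40 in cells picked by UMIs. The bone regulator Runx2 was at 1924 CPM in WT and 2270 in R76W, its target Sp7 at 27.5 and 17.8, Alpl at 60.5 and 56.4, and Col1a1 at 191 and 259 (log2 ratio 0.44, which was -0.06 over all mesenchymal cells). Spp1 was at 879 (857 to 901) CPM in WT and 368 (355 to 381) CPM in R76W (log2 ratio -1.25), and Bmp4 at 399 and 183 CPM (-1.12). Vdr, the vitamin D receptor gene, was at 26.8 and 50.5 CPM and Tnfsf11 (RANKL) at 162 and 280.1 CPM.

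Genes of prostaglandin E2 differed in opposite directions between R76W and WT. Hpgd, whose enzyme inactivates prostaglandin E2, was at 169 (159.6 to 179) CPM in WT and 62.1 (57.0 to 67.6) CPM in R76W (log2 ratio -1.43). The transporter gene Abcc4 was at 18.5 and 38.9 CPM and Slco2a1 at 7.19 and 12.6. Of the receptors, Ptger3 was at 12.3 (9.88 to 15.1) CPM in WT and 6.28 (4.72 to 8.20) in R76W, while the intervals of Ptger4 (26.7 and 30.7 CPM) and Ptger2 (2.07 and 3.49 CPM) overlapped. Within cluster 1 Ptger3 was at 13.9 CPM in WT and 13.7 in R76W, and its intervals were separated only within cluster 4 (19.7 and 3.03 CPM). The prostaglandin E2 list had a median of -0.11 at percentile 19.0. cAMP and CREB targets, some of which respond to prostaglandin E2, had a median of 0.47 at percentile 100, and 6 of 16 genes were at least 1.5 times higher in R76W, among them Nr4a1 (12.3 and 30.9 CPM), Pde4b (3.18 and 8.61), Nr4a3 (4.70 and 10.0) and Fosl2 (11.2 and 22.0).

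The 8 highest ratios were of Greb1, Frmd5, Ank3, Trpc6, Clstn2, Rnf144a, Zbtb16 and Nav2. Ratios of single genes are given here without the trend with gene length removed. The median log2 ratio of R76W against WT was -0.20 in the shortest group of genes (median 4.23 kb) and 0.15 in the longest (median 129.7 kb). The hormone-responsive gene Greb1 was at 4.84 CPM in WT and 29.4 CPM in R76W, and the membrane scaffold gene Ank3 at 166 and 622. Within cluster 2, Greb1 was at 1.49 CPM in WT and 43.9 in R76W, and without that cluster its log2 ratio went from 2.38 to 1.26. The transcription factor gene Zbtb16 was at 26.4 and 81.6 CPM. The 8 lowest ratios were of Hist1h2ae, Hist1h2ap, Cd24a, Hist1h1b, Ctse, Mki67, Birc5 and Rrm2, each at over 400 CPM in WT erythroid cells. Without genes higher in erythroid cells in every library, a choice made after the values were seen, the lowest were Wdr72, Cxcl10, Rerg, Syt6, Timp4, Hpgd, Plac9b and Gabrg3. The GTPase gene Rerg was at 51.3 CPM in WT and 12.3 in R76W. Cxcl10 was at 101 and 22.6 CPM, but 709 of its 732 WT UMIs lay in the 21 WT cells of cluster 18, and without that cluster its log2 ratio was 1.34.

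Interferon-response genes had a median of -0.33 at percentile 0, with 7 of 31 at least 1.5 times lower in R76W, among them Ifit3 (26.0 and 10.1 CPM) and Isg15 (106 and 59.6 CPM). Both are leading genes of cluster 18, whose 21 WT cells held 106 of the 188 WT UMIs of Ifit3, and without that cluster the median was -0.20. Within cluster 1 the WT and R76W intervals overlapped for Ifit3 (10.5 and 12.6 CPM) and Isg15 (104 and 90.8 CPM), and within cluster 2 both were lower in R76W, with Isg15 at 64.8 and 42.3 CPM. Isg15 was also lower in R76W than in WT in erythroid cells (35.9 and 15.2 CPM) and in monocytes or macrophages (40.3 and 17.3 CPM). Its intervals overlapped in osteoblasts of cluster 11 (7.79 and 5.65 CPM) and within LepR+ cluster 16 (74.3 and 113 CPM). In cluster 11 cells under 1% hemoglobin the interferon median was above WT, at 0.31 (percentile 99.55). Matrix genes had a median of 0.30 at percentile 100, with 3 of 38 genes at least 1.5 times higher and 1 lower, and Col8a1 was at 429 CPM in WT and 952 in R76W. Cholesterol synthesis genes had a median of -0.42 at percentile 0.0300, with Fdps at 18.1 and 4.30 CPM and 79.4 CPM in WT erythroid cells. The inflammatory list had a median of -0.26 at percentile 0.340, which was 0.14 with LepR+ clusters weighted equally and -0.06 (percentile 21.1) with the length trend removed. Cell cycle genes had a median of -1.64, nuclear oxidative phosphorylation genes of -0.46 and ribosomal protein genes of -0.41, with percentiles of 0, 0 and 0, and most genes of these lists were higher in erythroid than in LepR+ cells of WT. Stem or progenitor genes had a median of 0.25 (0.11 at percentile 93.3 with the length trend removed; Grem1 237 and 400.2 CPM), the Wnt list of 0.14 (Sfrp2 11.6 and 32.1 CPM), TGF-beta and BMP genes of 0.14, heat shock genes of 0.19 and the unfolded protein response of 0.11. Medians below WT were -0.14 for niche factors, -0.21 for senescence (-0.05 at percentile 28.9 with the length trend removed), -0.18 for oxidative stress and -0.14 for Notch, although Heyl was higher in R76W at 61.4 and 157 CPM. Osteoclast regulation (-0.03), glycolysis (-0.01), the IGF pathway (0.06) and sex-linked genes (-0.05) stood within 0.1 of WT. Immediate early genes (0.07) and mitochondrially encoded genes (0.05) did so only before the trend with gene length was removed, after which they were at 0.25 and 0.30, both at percentile 100. With that trend removed heat shock genes were at 0.36 and Notch genes at -0.25, at percentiles 100 and 0.970. The immediate early list shares Fos, Dusp1 and Nr4a1 with the cAMP list.

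D130 against WT asks how stromal cells differ when osteocyte hemichannels and gap junctions are both blocked. LepR+ cells of D130 had more RNA of Pparg and other adipogenic genes, of the chemokine genes Ccl2 and Ccl7, and of the chaperone genes Hspa5 and Calr. They had less of the bone matrix and mineral genes Mmp13, Alpl and Bglap and less of the growth factor gene Ptn, but not in every choice of cells for the last 3. Gja1 was higher than in WT, as in R76W. Cluster 1 was the largest LepR+ cluster in WT and in D130, with 29.7% and 48.2% of the cells.

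Gja1 was at 1173 (1149.5 to 1198) CPM in D130 against 737 (717 to 757) in WT (log2 ratio 0.67), and the same limit holds that stromal counts do not check an osteocyte transgene. Gja5 was at 4.15 and 9.64 CPM, and the connexin list had a median of 0.55 (percentile 100).

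Adipogenic genes had a median of 0.30 at percentile 100, with 5 of 30 genes at least 1.5 times higher and 1 lower in D130. That median was smaller in other cells taken, at 0.11 in LepR+ cells with at most 1 hemoglobin UMI and 0.15 over all mesenchymal cells. Pparg was at 444 (429 to 459) CPM in D130 against 267 (255 to 279) in WT, 1.66 times higher. Pparg was higher in D130 than in WT within clusters 1 (213 and 361 CPM), 4 (388 and 508 CPM), 16 and 18 but not within cluster 2 (282 and 267 CPM) or cluster 10 (211 and 202 CPM). The lipid-binding gene Fabp4, also an endothelial marker, was at 37.0 CPM in WT and 67.2 in D130, the lipid-droplet gene Plin1 at 2.07 and 6.30, and Cfd (adipsin) at 7.74 and 19.3. Adipoq, by contrast, was lower in D130 at 1180.1 CPM against 1520.1, and Lepr was at 1622 against 2132 CPM. Cxcl12 was at 17679 CPM in WT and 17441 in D130. Osteogenic genes had a median of -0.21 at percentile 0.0300, with 2 of 33 genes higher and 6 lower. That median was 0.13 over all mesenchymal cells and 0.44 in cells picked by UMIs of at least 2 of Cxcl12, Lepr, Adipoq and Kitl and none of Ptprc, so its sign depends on the cells taken. The collagenase gene Mmp13 was at 882 (861 to 904) CPM in WT and 411 (397 to 425) in D130, where it is a leading gene of cluster 10 with its smaller D130 share, and Alpl, whose enzyme frees phosphate for mineral, at 60.5 (55.0 to 66.5) and 28.9 (25.3 to 33.0). Runx2 was at 1924 and 1614 CPM, Sp7 at 27.5 and 21.5, Col1a1 at 191 and 214, and Spp1 at 879 and 1253. Bglap (osteocalcin) was at 48.4 CPM in WT LepR+ cells and 20.2 in D130, beside 16.8 CPM in WT erythroid cells. The log2 ratios of Alpl, Bglap and Ptn were -1.04, -1.22 and -2.41 in LepR+ cells but 0.17, 0.29 and 0.24 in cells picked by UMIs, and that of Ptn was 0.52 over all mesenchymal cells.

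Prostaglandin E2 genes had a median of 0.23 at percentile 98.8, with 3 of 12 genes at least 1.5 times higher and 1 lower, and the median was -0.33 when each cell was thinned to 2000 UMIs. The receptor gene Ptger4 was at 26.7 (23.0 to 30.7) CPM in WT and 42.9 (38.5 to 47.8) in D130. The intervals of Ptger2 (2.07 and 3.86 CPM) and Ptger3 (12.3 and 15.9 CPM) overlapped. Ptgs1, which encodes a cyclooxygenase, was at 1.52 and 5.79 CPM and Hpgd at 169 and 94.5. Ptgs2 and Ptger1 had too few UMIs to be measured in LepR+ cells. cAMP and CREB targets had a median of 0.18 (percentile 97.9), with Fosl2 at 11.2 and 36.1 CPM.

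The 8 highest ratios were of Ccl2, Zbtb16, Fabp5, Ankef1, Rgs5, Nab2, Phlda1 and Fosl2. The monocyte-attracting chemokine gene Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) was at 67.6 (61.7 to 73.9) CPM in WT and 494 (479 to 510.3) in D130, 7.31 times higher. Ccl2 was higher in D130 within cluster 1 (109 and 782 CPM) and within cluster 4 (27.8 and 120.2 CPM). Zbtb16 was at 26.4 and 163 CPM, and the fatty-acid-binding gene Fabp5 at 6.63 and 34.6. The 8 lowest ratios were of A2m and of Hist1h2ae, Hist1h2ap, Cd24a, Ctse, Hist1h1b, Mki67 and Rrm2, all but A2m at over 400 CPM in WT erythroid cells. Without genes higher in erythroid cells in every library the lowest were A2m, Ptn, Gadd45a, Hpse2, Zfp804b, Plac9b, Aldh1a2 and Wdr72. A2m, Aldh1a2 and Ptn were also leading genes of clusters 2 and 10, which held fewer D130 cells. Within cluster 2, Ptn was at 137 CPM in WT and 39.8 in D130. Gadd45a, a growth arrest gene, was at 69.0 and 15.4 CPM.

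Inflammatory chemokine and NF-kB genes had a median of 0.41 at percentile 100, with 10 of 22 genes at least 1.5 times higher and 0 lower in D130. Il1rn, the interleukin 1 antagonist gene, was at 179 and 512 CPM, Ccl7 at 18.8 and 54.3, and Saa3 at 2.21 and 10.0. Monocytes or macrophages, which express some of these genes, were 5.88% of D130 cells, and their markers summed to 80.6 CPM in D130 LepR+ cells against 45.3 in WT. Osteoclast regulation genes had a median of 0.48 (percentile 100), where Tnfsf11 was lower in D130 at 115 against 162 CPM. The unfolded protein response had a median of 0.35 (percentile 100), with 5 of 18 genes at least 1.5 times higher and 2 lower, and heat shock genes of 0.35 (percentile 100), with 5 of 15 higher and 0 lower. Hspa5 was at 953 and 1500.4 CPM, Calr at 392 and 739, Xbp1 at 131 and 237, and Dnaja1 at 231 and 461. The metallothionein genes Mt1 (138 and 366 CPM) and Mt2 (30.4 and 92.7 CPM) were higher in D130, while oxidative stress genes as a list had a median of -0.09. Wnt genes had a median of -0.17 (percentile 1.14), with Dkk3 at 52.4 and 27.8 CPM, and the median was -0.11 (percentile 4.74) with the length trend removed and positive (0.06) in cells picked by UMIs. Notch genes had a median of 0.13 although Hes1 was lower, at 285 CPM in WT and 156 in D130, and the IGF pathway stood at 0.00 with Igfbp5 at 10302 and 6598 CPM. Interferon genes had a median of 0.16, TGF-beta and BMP genes of 0.13, cholesterol synthesis of 0.13, niche factors of 0.10, matrix genes of 0.09, immediate early genes of 0.09, stem or progenitor genes of 0.06, mitochondrially encoded genes of 0.13 and sex-linked genes of 0.07. With the length trend removed, immediate early genes were at 0.19 (percentile 99.7), mitochondrially encoded genes at 0.28 (percentile 99.8), cholesterol synthesis at 0.20 (percentile 98.4) and TGF-beta and BMP genes at 0.07 (percentile 87.9). Cluster 1, led by immediate early genes, held a larger share of D130 than of WT LepR+ cells. Within it Fos was at 2924 CPM in WT and 1235.5 in D130, and Jun at 1417 and 1047.5. Fos was also lower in D130 within clusters 10 and 18, and higher within clusters 2 and 16. Below WT stood senescence genes (-0.13, or -0.02 with the length trend removed), glycolysis (-0.07), cell cycle genes (-1.28), oxidative phosphorylation (-0.26) and ribosomal protein genes (-0.25). With erythroid RNA subtracted, cell cycle genes were at 0.09 and ribosomal protein genes at 0.01, so neither was below WT. In LepR+ cells with at most 1 hemoglobin UMI they were at 0.29 and -0.02.

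**Figure D2:**
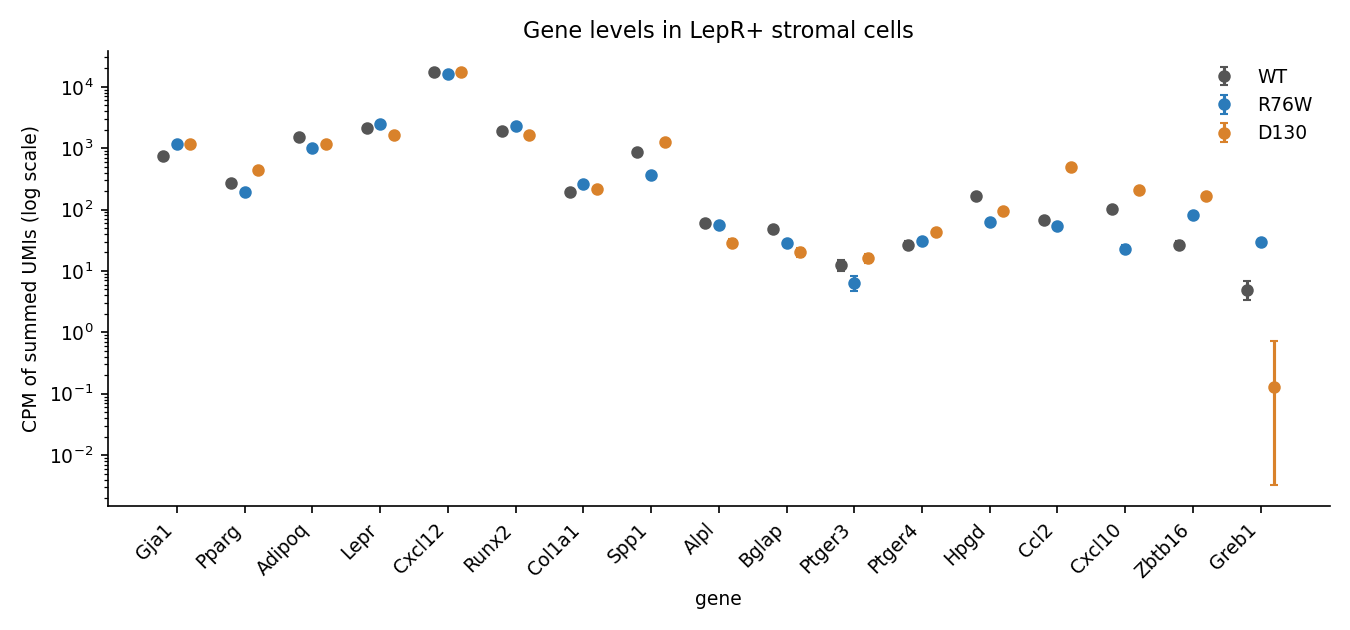
CPM of summed UMIs on a log axis for 17 genes in LepR+ stromal cells of WT, R76W and D130, 1 point per library with exact Poisson 95% intervals. Ccl2 stands at 494 CPM in D130 against 67.6 in WT, and Gja1 is higher in both mutant libraries than in WT.

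D130 against R76W asks what differs when hemichannels are blocked in addition to gap junctions. LepR+ cells of D130 had more RNA of the adipocyte regulator Pparg, of chemokine and interferon-response genes such as Ccl2 and Isg15, of Spp1 and of cholesterol synthesis genes such as Fdps than those of R76W. They had less of the bone-resorption signal Tnfsf11, of Mmp13 and of Greb1, Ank3 and Aldh1a2. Gja1 summed over the LepR+ class did not differ beyond counting error between the mutant libraries, although it differed in both directions within clusters. Cluster 1 was the largest LepR+ cluster in D130 and cluster 2 in R76W.

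Gja1 was at 1173 CPM in D130 and 1174 in R76W, a ratio of 1.00 (0.972 to 1.03). Within clusters, R76W and D130 were at 1013 and 1221 CPM of Gja1 in cluster 1 and at 1129 and 1619 in cluster 10. The order was opposite in cluster 2 (1252 and 1045 CPM) and cluster 16 (1291 and 817 CPM), and the intervals overlapped in clusters 4 and 18. Pparg was 2.26 (2.13 to 2.40) times higher in D130, and it was higher in D130 within cluster 1 (154 CPM in R76W and 361 in D130), cluster 2 (196 and 267 CPM), cluster 4 and cluster 16. The intervals of Pparg overlapped in clusters 10 and 18. The adipogenic list had a median of 0.26 at percentile 100, with 6 of 30 genes at least 1.5 times higher and 2 lower. That median was 0.03 over all mesenchymal cells, 0.06 without cluster 2 and -0.02 in cells picked by UMIs. Plin1 was at 1.40 CPM in R76W and 6.30 in D130, and Cfd at 0.465 and 19.3. The osteogenic list had a median of -0.21 at percentile 0, and of 0.30 over all mesenchymal cells. Spp1 was at 368 CPM in R76W and 1253 in D130, Mmp13 at 1041 and 411, and the phosphate regulator Phex at 219 and 91.7. Tnfsf11 was at 280.1 CPM in R76W and 115 in D130, and Runx2 at 2270 and 1614. The prostaglandin E2 list had a median of 0.12 at percentile 87.3, with Ptger3 at 6.28 (4.72 to 8.20) CPM in R76W and 15.9 (13.3 to 19.0) in D130, Ptger4 at 30.7 and 42.9, Ptges at 9.89 and 16.1, and Abcc4 at 38.9 and 19.7. Within cluster 1 Ptger3 was at 13.7 CPM in R76W and 10.8 in D130, and within cluster 2 at 2.77 and 2.34, with overlapping intervals. It was higher in D130 beyond counting error only within cluster 4 (3.03 and 25.4 CPM) and cluster 16 (1.80 and 20.3 CPM). cAMP and CREB targets had a median of -0.26 (percentile 0.0800), with Nr4a1 at 30.9 and 10.4 CPM.

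The 8 highest ratios were of Ccl2, Cxcl10, Ankef1, Rgs5, Fabp5, Cxcl1, Rerg and Rassf4, and the 8 lowest of Greb1, Ppm1n, Camk4, Aldh1a2, Ptn, A2m, Nav2 and Ank3. Cxcl10 lay mostly in the small cluster 18, and its log2 ratio of 3.13 was -1.06 with LepR+ clusters weighted equally, which leaves that cluster out. Ccl2 was 9.08 (8.25 to 10.0) times higher in D130, and Cxcl1 was at 4.42 CPM in R76W and 24.4 in D130. Greb1 had 253 UMIs in R76W and 1 in D130, a ratio of 0.00437 (0.00011 to 0.0246). Within cluster 1, Greb1 was at 16.0 CPM in R76W and 0.269 in D130. The kinase gene Camk4 was at 33.6 and 2.44 CPM, and Ank3 at 622 and 127. The inflammatory list had a median of 0.60 (percentile 100), the interferon list of 0.46 (percentile 100) with Isg15 at 59.6 and 158 CPM, and cholesterol synthesis of 0.61 (percentile 100) with Fdps at 4.30 and 13.9 CPM. Heat shock genes stood at 0.45, the unfolded protein response at 0.44, osteoclast regulation at 0.32, Wnt genes at -0.21 and matrix genes at -0.13, the last with 0.08 over all mesenchymal cells.

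**Figure D3:**
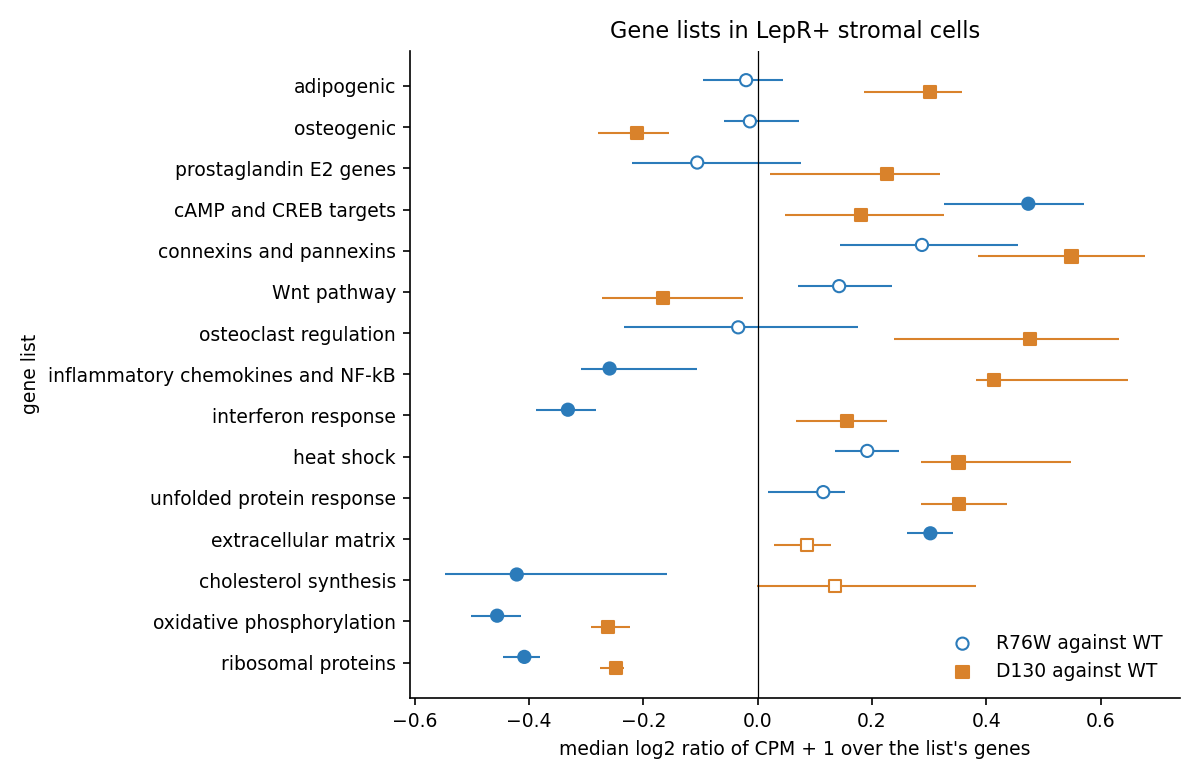
Median log2 ratio of CPM plus 1 over the measured genes of 15 lists in LepR+ stromal cells, R76W against WT (circles) and D130 against WT (squares), with lines for the 95% range of Poisson draws and filled marks for medians in the outer 5% of matched random lists. The adipogenic median was 0.30 for D130 and -0.02 for R76W.

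Osteolineage cells were compared in each of their clusters, since cluster 11 took a larger part of the class in R76W and D130 than in WT. Osteoblasts of cluster 11 secrete collagen I and osteocalcin. In D130 these osteoblasts had less RNA of Bglap and of immediate early genes such as Fos and more of the matrix genes Col3a1 and Fmod than in WT. Cluster 5 of R76W had less Spp1 and Wif1, a Wnt inhibitor gene, than in WT.

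Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464) was at 73195 (72905 to 73485) CPM in WT osteoblasts, 83653 (83316 to 83991) in R76W and 25673 (25521 to 25826) in D130. The median of all measured genes in cluster 11 stood at 0.21 for D130 against WT, and Bglap relative to it was -1.73 on the log2 scale. The other values for cluster 11 are given without taking that shift off. Bglap2 and Bglap3 are near-identical copies, which leaves the assignment of reads between them uncertain, and the 3 copies summed to 100510.0 CPM in WT, 120310.0 in R76W and 35947 in D130. Col1a1 was at 94117 CPM in WT, 103860 in R76W and 92368 in D130, Ibsp at 5152, 4599.7 and 3442, and Runx2 at 522, 609 and 1097. Gja1 was at 499, 748 and 930.2 CPM. Immediate early genes had a median of 0.82 for R76W and -1.06 for D130, with Fos at 1056 CPM in WT, 1708 in R76W and 435 in D130, Egr1 at 277, 614 and 132, and Atf3 at 159, 299 and 48.3. These genes also respond to cell dissociation. The list member Nfkbia was at 81.2 CPM in WT and 29.7 in D130 osteoblasts. It was also lower in D130 in erythroid cells (61.2 and 16.3 CPM) and in monocytes or macrophages (357 and 80.8), but not in LepR+ cells (196 and 208). Dusp1 was also lower in D130 in erythroid cells (25.9 and 12.8 CPM), and its intervals overlapped in monocytes or macrophages (132 and 110). Lower levels of these genes in D130 were thus not particular to osteoblasts. Matrix genes had a median of 0.61 for D130, where Col3a1 was at 70.1 CPM in WT and 353 in D130 and Fmod at 14.99 and 75.2. Ptn was at 12.6 and 129.8 CPM, the opposite order to LepR+ cells. In R76W the highest ratios were of Hp, Cxcl12, Igfbp5 and Vcam1, which LepR+ cells express strongly, with Cxcl12 at 20.7 CPM in WT and 216 in R76W.

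The R76W osteolineage share of 17.8% was 10.8% to 14.0% in 7 of 10 other settings and 7.19% with each library clustered on its own, so the R76W values of cluster 5 belong to cells whose number depends on the clustering. In cluster 5, Spp1 was at 10639 (10514 to 10765) CPM in WT, 3855 (3756 to 3957) in R76W and 10976 (10839 to 11113) in D130, and Wif1 at 1234, 745 and 968. Smpd3 was at 37.6 CPM in WT, 3.39 in R76W and 40.5 in D130, Ccnd1 at 27.5, 2.03 and 34.7, and Npy at 165, 12.2 and 161. The osteogenic list had a median of -0.21 (percentile 1.41) for R76W and -0.05 (percentile 23.4) for D130, while Col1a1 was at 1771 CPM in WT and 3592 in D130. The osteocyte gene Dmp1 was at 122 CPM in WT, 48.1 in R76W and 36.9 in D130. Cholesterol synthesis genes had a median of -0.90 for R76W and 0.14 for D130, and the unfolded protein response of 0.48 for D130. In D130 the highest ratios were of Aspn (7.74 CPM in WT and 98.8 in D130) and Igf2 (3.48 and 21.8), and the lowest of Greb1, Aldh1a2, Fam189a1, Tll2 and A2m together with the erythroid gene Cd24a.

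**Figure D4:**
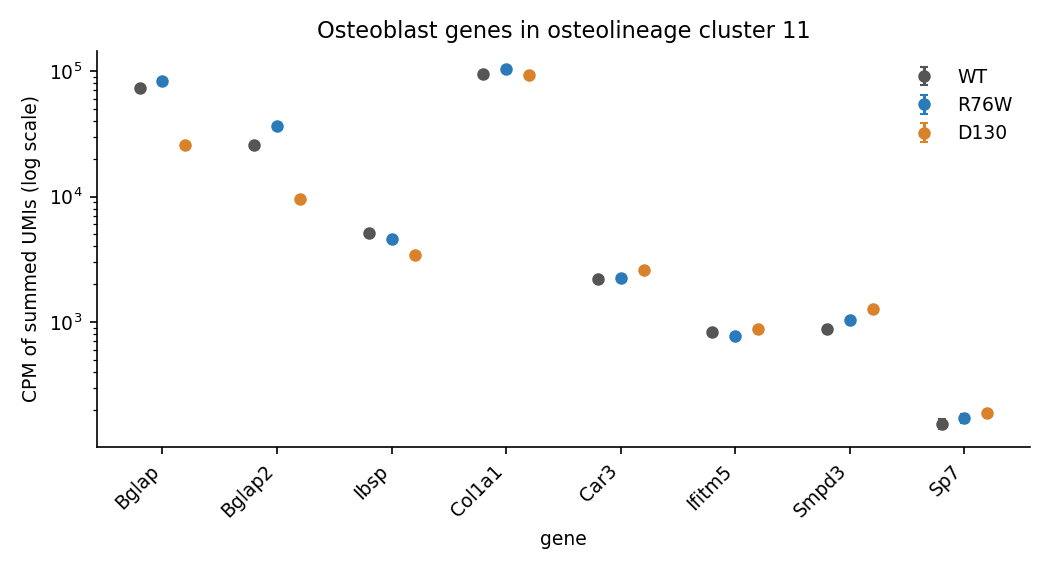
CPM of summed UMIs on a log axis for 8 osteoblast genes in osteolineage cluster 11 of WT (130 cells), R76W (90 cells) and D130 (134 cells), 1 point per library with exact Poisson 95% intervals. Bglap stands at 25673 CPM in D130 against 73195 in WT, while Col1a1 differs by less than 1.2 times among the libraries.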

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

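The tests with erythroid RNA subtracted, with the gene length trend removed, of hemoglobin in cells with cell cycle UMIs, and of mature osteoblast markers and summed Bglap copies were chosen only after the result was seen. LepR+ cells with at most 1 hemoglobin UMI were also chosen after the list medians were seen, although the bounds for them were written before their values. The tests of Bglap by medians over cells and at equal depth were set before their values were seen.

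Cell cycle genes were lower in LepR+ cells of R76W (-1.64) and D130 (-1.28) than of WT. Fewer cycling LepR+ cells in the mutant libraries are argued against by hemoglobin: the 16 WT LepR+ cells with many cell cycle UMIs held a median of 145 hemoglobin UMIs, a ratio of 145 to the median of 1 in the others. With erythroid RNA subtracted the medians were -0.078 for R76W and 0.088 for D130, and in LepR+ cells with at most 1 hemoglobin UMI they were -0.33 and 0.29. Erythroid RNA or erythroid doublets in the WT library are a candidate explanation. The sort stain included Ter119 and predicted doublets were removed, but neither step speaks strongly against it. Erythroid cells were still 54.1% of WT cells, and the automatic doublet threshold marked 0 WT cells, so only the top scores were removed. Smaller differences in cycling stay open.

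Ribosomal protein genes (-0.41) and nuclear oxidative phosphorylation genes (-0.46) were lower in LepR+ cells of R76W than of WT. A trend with gene length as the whole cause is argued against, since with it removed the lists stood at percentiles 0.12 and 0 of random lists, but part of the difference went with length, to -0.17 and -0.34. For ribosomal protein genes, erythroid RNA in the WT library is a candidate explanation, with medians of -0.081 after its subtraction and -0.070 in cells with at most 1 hemoglobin UMI. For oxidative phosphorylation genes erythroid RNA does not account for the whole difference, with medians of -0.37 and -0.34 in the same tests. A difference between the libraries in cell handling, and one from the genotype, stay open for the latter and were not tested.

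Bglap was lower in osteoblasts of cluster 11 in D130 than in WT, at -1.73 relative to all genes. Reads moved between copies are argued against by the summed copies, at -1.48. A few WT cells with very high Bglap are argued against by the medians over cells, with a log2 ratio of -2.79, and depth by cells thinned to 5000 UMIs, at -1.60. The values of -1.48, -2.79 and -1.60 are without the shift of all genes (0.21) taken off, so they cannot be set against -1.73. Fewer mature cells cannot be told apart from a lower Bglap level: 6 other osteoblast genes had a median of -0.055 relative to all genes but went both ways, with Ibsp lower (3442 CPM in D130 and 5152 in WT) and Smpd3 higher, and Runx2, Col3a1 and Prrx1 were higher in D130. The 6 genes were picked from the cluster's own class, and the genotype and sample handling stay open too, since each genotype was 1 library.

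The following results were picked out because the LepR+ and the osteolineage class had opposite directions in the same comparison, and the difference was not tested. For D130 against WT, the LepR+ median minus the osteolineage median was 0.67 for adipogenic genes (0.30 and -0.37), 0.51 for cAMP and CREB targets (0.18 and -0.33), 0.42 for interferon genes (0.16 and -0.26) and 0.32 for TGF-beta and BMP genes (0.13 and -0.19). For D130 against R76W it was 0.47 for adipogenic genes (0.26 in LepR+ cells). The class pools clusters 5 and 11, and cluster 11 was 28.0% of it in WT, 39.8% in R76W and 42.8% in D130. Within clusters 5 and 11, the D130 against WT medians were -0.17 and 0.20 for adipogenic genes, -0.039 and -0.13 for cAMP and CREB targets, -0.064 and 0.0098 for interferon genes and -0.016 and 0.065 for TGF-beta and BMP genes, while the median of all genes in cluster 11 stood at 0.21. In cluster 11 cells under 1% hemoglobin the same 4 medians were 0.25, -0.29, 0.20 and -0.065, so TGF-beta and BMP genes alone changed sign with the cells taken. The cAMP and CREB median was negative in both choices. The adipogenic and interferon medians were positive in both, but in cells under 1% hemoglobin they stood at percentiles 54.9 and 47.0 of random lists. For D130 against R76W the adipogenic medians were -0.24 in cluster 5 and -0.45 in cluster 11.

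Other values were picked out from cells and barcodes that the comparisons did not use. The share of barcodes rich in mitochondrial UMIs was picked because it lay above WT. The genes had the highest erythroid ratios to WT among genes within the limits for named genes, Mid1 and Camk1d for R76W and Hist1h4n and Hsph1 for D130. Barcodes with over 50% mitochondrial UMIs were 35.0% in R76W and 41.2% in D130, against 24.6% (23.6 to 25.6) in WT. In erythroid cells of WT, R76W and D130, Mid1 was at 20.2, 74.2 and 7.41 CPM, Camk1d at 346, 1073 and 633, Hist1h4n at 37.9, 88.3 and 128, and Hsph1 at 47.7, 119 and 122. Camk1d had the same order in LepR+ cells (760, 1663 and 950 CPM), monocytes or macrophages (299, 807 and 567) and cluster 11 (504, 1033 and 784). Hsph1 was at 16.3, 29.6 and 44.9 CPM in LepR+ cells, at 15.7, 37.0 and 37.7 in monocytes or macrophages and at 14.4, 10.9 and 22.9 in cluster 11. The differences of Camk1d and Hsph1 were thus not particular to erythroid cells.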

How the results depend on the processing

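Alternatives on cell limits, doublets, resolution, separate clustering, thinning, UMI minimum, scaling, pseudocount and cells taken were set before the data were examined. The tests with other naming, clustering without marker genes, erythroid RNA subtracted, few hemoglobin UMIs, equal cluster weights, without cluster 2 or 18, and with the length trend removed were chosen only after the result was seen. No paired analysis was possible because each genotype had 1 library. Where a cause is not named, the cause was not tested.

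Shares kept R76W highest in mesenchymal and LepR+ cells and lowest in osteolineage cells in each of 10 alternatives, but 61 of 90 values moved beyond counting error. With at most 5% mitochondrial UMIs, LepR+ cells of WT, R76W and D130 were 77.3%, 85.5% and 78.3% of mesenchymal cells and osteolineage cells 20.4%, 12.4% and 19.96%, and the adipogenic median for D130 against WT was 0.18. With at most 20% the shares were 78.2%, 85.2% and 78.1%, and 19.8%, 12.9% and 20.2%. With at least 1000 genes and 2000 UMIs, WT had 42.0% mesenchymal cells, and the shares were 78.8%, 87.1% and 79.6%, and 19.0%, 10.8% and 18.7%. With at least 200 genes and 500 UMIs, mesenchymal cells were 33.5%, 65.6% and 55.1%, Bglap in LepR+ cells for R76W against WT was reversed from -0.77 to 0.18, and the osteogenic median for D130 against WT was -0.15. With doublets kept, LepR+ shares were 77.2%, 84.1% and 77.8%, osteolineage shares 20.7%, 14.0% and 20.4%, and the osteogenic median for D130 against R76W -0.10. At Leiden resolution 0.5 the shares were 77.3%, 85.3% and 77.5%, and 20.6%, 12.7% and 20.7%. At resolution 2 they were 77.6%, 85.5% and 79.1%, and 20.4%, 12.6% and 19.1%. Clustered without marker genes, they were 79.0%, 86.3% and 78.8%, and 18.8%, 11.6% and 19.4%. With each library clustered on its own, they were 78.4%, 91.0% and 80.0%, and 19.6%, 7.19% and 18.0%, the osteogenic medians were 0.36 for R76W against WT, -0.10 for D130 against WT and -0.42 for D130 against R76W, and Bglap for R76W against WT was 0.23.

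With clusters named by leading genes over all other cells, which leaves clusters 8, 10 and 16 unnamed, mesenchymal cells were 33.9%, 59.8% and 52.0%, LepR+ cells 65.2%, 76.3% and 70.0%, and osteolineage cells 32.4%, 21.3% and 28.1%. The adipogenic medians were then -0.10 for R76W against WT, 0.17 for D130 against WT and 0.14 for D130 against R76W, the osteogenic median for D130 against WT -0.11, and Cxcl12 for D130 against WT 0.0068.

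In cells picked by UMIs of Cxcl12, Lepr, Adipoq and Kitl without Ptprc, R76W against WT gave 0.11 for adipogenic and 0.40 for osteogenic genes, 0.17 for Cxcl12 and 1.36 for Bglap. D130 against WT gave 0.44 for osteogenic and 0.055 for Wnt genes, 0.17 for Alpl, 0.29 for Bglap and 0.24 for Ptn. D130 against R76W gave -0.016 for adipogenic and 0.17 for osteogenic genes, -0.16 for Adipoq, -0.24 for Cxcl12, 0.15 for Alpl and 0.19 for Col1a1. Over all mesenchymal cells, R76W against WT gave -0.071 for osteogenic genes, 0.038 for Cxcl12 and -0.062 for Col1a1. D130 against WT gave 0.15 for adipogenic and 0.13 for osteogenic genes and 0.52 for Ptn. D130 against R76W gave 0.025 for adipogenic, 0.30 for osteogenic and 0.080 for matrix genes, -0.094 for Adipoq, -0.17 for Cxcl12, 0.20 for Alpl and 0.27 for Col1a1. Both choices take in cells of other classes by construction.

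With each cell thinned to 2000 UMIs, which left out 76 WT, 22 R76W and 16 D130 cells, the prostaglandin E2 median was -0.22 for R76W against WT and was reversed to -0.33 for D130 against WT, and the osteogenic median for D130 against WT was -0.32. With erythroid RNA subtracted, D130 against WT gave 0.088 for cell cycle genes and 0.0086 for ribosomal protein genes. In LepR+ cells with at most 1 hemoglobin UMI it gave 0.11 for adipogenic genes, 0.29 for cell cycle genes and 0.64 for Hist1h1b, and the adipogenic median for D130 against R76W was 0.13.

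With 5 LepR+ clusters weighted equally, inflammatory genes for R76W against WT were at 0.14 and Cxcl10 at 2.37, which leaves out cluster 18 by construction. The osteogenic median for D130 against WT was -0.10 and Cxcl12 0.051, and for D130 against R76W the adipogenic median was 0.13 and Cxcl10 -1.06. Without cluster 2 the adipogenic medians were 0.11 for R76W against WT and 0.061 for D130 against R76W, and the osteogenic medians -0.30 for D130 against WT and -0.30 for D130 against R76W. Without cluster 18, Cxcl10 for R76W against WT was 1.34. With the length trend removed, Cxcl12 for D130 against WT was 0.0022 and the adipogenic median for D130 against R76W 0.17.

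Over all 26 alternatives and the reported value, the adipogenic median for D130 against WT was positive, from 0.11 to 0.33. The osteogenic median ranged from -0.32 to 0.44 for D130 against WT, from -0.42 to 0.30 for D130 against R76W and from -0.07 to 0.40 for R76W against WT, so no direction of the osteogenic list held across the alternatives. The prostaglandin E2 median ranged from -0.33 to 0.25 for D130 against WT. Among 9 medians of these 3 lists, 202 of 234 values stayed within counting error, 26 moved and 6 reversed. Among 72 other list medians 1537 of 1872 values stayed, 329 moved and 6 reversed, and among 107 gene ratios 1922 of 2770 stayed, 823 moved and 25 reversed. Of 45 levels of other cells' markers with doublets kept, 39 stayed and 6 moved. Few UMIs left some prostaglandin genes unmeasured, with Ptgs2 at 0, 0 and 8 UMIs and Ptger1 at 1, 2 and 0 UMIs in LepR+ cells of WT, R76W and D130.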

Other observations

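The tests of glucocorticoid-responsive genes were chosen only after the result for Zbtb16 was seen. Zbtb16, which glucocorticoids induce in many cells, was higher in LepR+ cells of both mutant libraries than of WT, with log2 ratios of 1.59 for R76W and 2.58 for D130. A wider difference in glucocorticoid response may explain it. The median over 9 other responsive genes was 0.27 for R76W and 0.51 for D130, and the bounds set for the test asked for over 0.3 in both, so the hypothesis could not be decided. Errfi1 was at 527 CPM in WT, 822 in R76W and 1078 in D130 and Fkbp5 at 96.1, 111 and 166, while Dusp1 was at 257, 229.6 and 161. Both comparisons share the WT library, so they are not independent.

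Cxcl10 in LepR+ cells lay mostly in cluster 18, which held 21 WT, 5 R76W and 25 D130 cells, with 709 of 732 UMIs in WT and 1463 of 1602 in D130. In erythroid cells, Hist1h4m had 1963 UMIs in WT, 0 in R76W and 1 in D130, while Hist1h4n had 2036, 981 and 2784, or 37.9, 88.3 and 128 CPM. Hist1h4m had 47, 0 and 0 UMIs in monocytes or macrophages, 10, 0 and 0 in LepR+ cells and 8, 0 and 0 in osteoblasts of cluster 11. Its near absence from the mutant libraries was thus not particular to erythroid cells. Both are histone H4 genes. In monocytes or macrophages of WT, R76W and D130, Hist1h4m was at 35.1, 0 and 0 CPM and Hist1h4n at 29.1, 63.7 and 62.4. In LepR+ cells Hist1h4n was at 2.21, 2.21 and 2.96 CPM, with overlapping intervals. Whether reads were assigned differently between the genes was not tested, so the level of Hist1h4n alone does not show more histone H4 RNA in the mutant libraries. Mid1 on chromosome X was at 20.2, 74.2 and 7.41 CPM in erythroid cells of WT, R76W and D130, at 23.9, 75.5 and 13.4 in monocytes or macrophages, at 12.6, 31.1 and 13.2 in osteoblasts of cluster 11 and at 538, 620 and 579 in LepR+ cells. The median of all genes in erythroid cells stood at 0.27 for R76W and 0.14 for D130 against WT.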
